A study of Caenorhabditis elegans with 2 samples.

How the data were processed

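Chromatin immunoprecipitation followed by sequencing was carried out with an anti-GFP antibody on whole L2 larvae of a transgenic Caenorhabditis elegans strain. Per the labels, the strain carried an integrated transgene with Y55F3AM.14 fused at its C terminus to eGFP and a FLAG tag, together with an unc-119 rescue marker in an unc-119 mutant background. The animals were of mixed sex, were synchronised by bleaching and starvation at L1 and were collected at 42 hours, and chromatin was sonicated to 200 to 800 bp, per the labels. There was 1 group of 2 samples, which the labels call biological replicates 1 and 2. The reference annotation names Y55F3AM.14 as znf-782, a gene for a C2H2-type zinc finger protein.

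The analysis started from 4 peak lists that the authors deposited in narrowPeak format on build ce11, which has the coordinates of WBcel235. Per the README deposited with the samples, a relaxed list of peaks and background was made from the alignments of each replicate and 1 control, a pooled relaxed list from the alignments of both replicates and 1 control, and an optimal list by an irreproducible discovery rate threshold from both replicate lists and the pooled list. The aligner, the peak caller, their versions and the threshold are not given in the sources used here. Each peak carries a score, the signal value given by the authors' caller, which was used to rank, filter and describe peaks within a list. The deposited lists also give the −log10 of the caller's q value. It ran from 0.0178 to 2.78 in the pooled list and from 1.60 to 2.78 in the optimal list. The summit, the position used for every distance below, was taken from the offset column that the authors deposited in the same lists. Totals of reads per sample are unknown here, so no value below is scaled to sequencing depth, and scores of different lists were not compared in size except between the replicates, where they are given side by side as the caller's own values. Control libraries, alignments and signal tracks were not used here.

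The 1604 regions of the optimal list are called optimal regions below, and N stands for their number. The 27586 regions of the pooled list that overlap no optimal region are called weaker regions and served as the background for location, because they came from the same libraries and control. The pooled list holds background as well as peaks, so weaker regions need not be binding sites. The optimal list held exactly the 1604 regions with the highest scores of the pooled list, and 439 further pooled regions overlapped an optimal region and were left out of both sets. Most regions had 1 fixed width, 424 bp, which 93.2% of the optimal regions shared. No line was identical between the replicate lists.

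Genes, transcript starts and the genome sequence came from the RefSeq annotation of WBcel235, whose header names WormBase as its source, and all coordinates are 1-based. A gene counted as having a region when an optimal summit lay within 500 bp of any of its annotated transcript starts, on either side, so that 1 region between divergent genes counted for both. The promoter share is the share of summits within 500 bp of a protein-coding start. The arm share is the share of autosomal summits in the outer parts of a chromosome divided into 3 equal lengths. Both, and the share on X, were compared between optimal and weaker regions with the two-sided Fisher's exact test, and 0.5 was added to each cell for the odds ratio. Replicate overlap is the share of the N highest-scoring regions of replicate 1 with a summit within 100 bp of one among the N highest-scoring regions of replicate 2. It was compared with 1000 random rotations of replicate 2 within its chromosomes, one-sided. Spearman's rho was computed across optimal regions, which are not independent replicates, with no p-value.

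The 27 lists of gene families, complexes and tissues were fixed as patterns of gene symbols, and each was tested against all other protein-coding genes on the nuclear chromosomes with the two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the lists. The 9 annotated classes of non-coding RNA genes with at least 20 members were tested against protein-coding genes in the same way. For sequence, presence of each of 2080 6-mers, a 6-mer and its reverse complement counted as 1, was compared between the 75 bp on each side of the optimal summits and a window of the same length centred 400 bp to one side, chosen at random, with the exact McNemar test and Benjamini-Hochberg adjustment. A list, class or 6-mer was called at an adjusted p under 0.05. The density of pooled relaxed peaks within 20 kb of znf-782 and of unc-119 was given as a percentile among protein-coding genes. Genes and regions are not replicates: the p-values measure scatter across genes or regions of this data set, and the replicates enter through their own lists. Intervals are 95% exact (Clopper-Pearson) intervals and cover counting error only.

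Genes were named by rule: the gene with the nearest start to each of the 15 strongest optimal regions, with both genes of a divergent pair; the 4 members with the strongest regions of each called list; up to 2 such members of every other list; and the tagged and rescue genes. The 5 enriched 6-mers with the lowest p were named. Other names were chosen after their values were seen: the remaining members of short counts, the non-coding genes with the strongest regions, genes with several regions and the 3 depleted 6-mers. Groups, gene lists, the naming rules, most tests and most alternative settings were fixed before the data were examined. The test over classes of sequence (exons, introns and intergenic sequence) was not among them. Antisense RNA genes were not named among the fixed non-coding classes. The percentile around znf-782 and unc-119 was fixed as a count of peaks but computed as a density per length. The tests were otherwise run as fixed. The alternatives were a stricter list, each replicate alone, other distances and backgrounds, other sequence windows and controls, and other spans around the tagged gene.

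Copy number was measured as whether every 31-mer in the 151 bp around a summit occurs once in the genome. Scripts were run with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The tests were tested on simulated data first. With 25% of the genes of 3 lists given a region among rotated optimal regions, tested over 19971 protein-coding genes, 59 of 60 planted lists were called, and rotated regions alone gave 0 called lists per rotation. Lists with a smaller planted share, or with fewer regions than other genes, were not simulated, so recovery of such lists was not tested. A 6-mer planted in 15% of random windows was called along with 5 others, and 0 were called without it. The random windows were not given the GC difference between optimal summits (mean 47.2%) and flanks (35.2%). Calls that follow from base composition were therefore not tested by this simulation. A planted replicate overlap of 60% was recovered as 60.3%.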

Results

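Binding of Y55F3AM.14-eGFP was profiled by ChIP-seq in 2 biological replicates of whole L2 larvae, to map where the tagged protein associates with the genome. The relaxed lists held 29577 regions in replicate 1, 28681 in replicate 2 and 29629 for both together, and the optimal list held 1604. Scores in the optimal list ran from 110.3 to 1466, with a median of 150.2. The sequencing depth behind each list is unknown. With 1 group the data allow comparisons between the replicates, between optimal and weaker regions and between groups of genes.

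The strongest optimal region lay in intergenic sequence on chromosome I (4297922 to 4298401), with its summit 52 bp upstream of scpl-3, which encodes a protein with an FCP1 phosphatase homology domain. Its score was 1466 in the pooled list, 786.6 in replicate 1 and 686.7 in replicate 2. The second and the fourth lay in introns of ppfr-1, a gene for a regulatory subunit of protein phosphatase 4, at I:9382817-9383294 (score 1438) and I:9381066-9381968 (839.8). The third lay between genes at III:3867416-3867717, with a score of 1052 and a summit 283 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Among the 15 strongest regions, ribosomal protein genes stood beside 3: rpl-3, rpl-15 (IV:654802-655054, score 762.0, between rpl-15 and K11H12.8) and rpl-18A (IV:4749949-4750213, score 752.0, between rpl-18A and Y17G9B.5).

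Other strong regions lay upstream of tasp-1, a TASPase homolog (III:10759093-10759386, score 832.6), sec-61.G, a subunit of the protein translocation channel of the endoplasmic reticulum (V:10897239-10897472, 726.0), and cbp-1, a homolog of the CBP/p300 acetyltransferases (III:9765518-9765753, 676.1, summit 882 bp upstream). Introns held the summits assigned to T28B11.1, a gene for an F-box domain protein (V:10715830-10716144, 793.0), pqn-41 (III:1925130-1925532, 762.0) and trd-1 (III:7387353-7387622, 664.5). Some strong summits were far from any protein-coding start. The nearest start was 4775 bp away for the region assigned to the calmodulin gene cmd-1 (V:1151382-1151661, 756.1), 5904 bp for saeg-1 (V:10871497-10871770, 722.0) and 2106 bp for sup-26, which encodes an RNA-binding protein (III:4281983-4282570, 648.2). All 73 named pairs of a gene and its region had a summit in both replicate lists.

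The comparison between replicates asked how far separate samples gave the same regions. Of the 1604 highest-scoring regions of replicate 1, 1005 (62.7%, 95% interval 60.2 to 65.0) had a summit within 100 bp of one among the 1604 highest-scoring regions of replicate 2. Rotated lists shared 0.327% on average and at most 1.31% (one-sided permutation p = 0.001, the smallest that 1000 rotations can give). Rotation compares only with random placement, so this test does not separate shared binding from background that recurs in both samples. The shared fraction was 74.0% for the top 100 regions, 69.4% for the top 800, 50.3% for the top 3208 and 39.96% for the top 6416. Of the top 1604, 195 in replicate 1 (12.2%) and 211 in replicate 2 (13.2%) had no region of the other replicate's full list within 100 bp.

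Of the 1604 optimal regions, 1517 (94.6%) had a summit in both replicate lists and 2 had one in neither. This share is not independent of the replicates, because the optimal list was derived from them. Across those 1517 regions the scores of the replicates had a Spearman rho of 0.589, and a rho of 0.796 over the 100 strongest. Both sets were selected by the pooled score, to which both replicates contributed. The rho values depend on that selection and do not measure agreement over all regions. Among named genes, regions with unlike scores in the replicates included that of unc-62, a homeobox gene (101.1 in replicate 1 and 33.5 in replicate 2), at rank 787 of the optimal list. Another was that of srh-16, a chemoreceptor gene (34.8 and 87.4), at rank 1249.

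**Figure D1:**
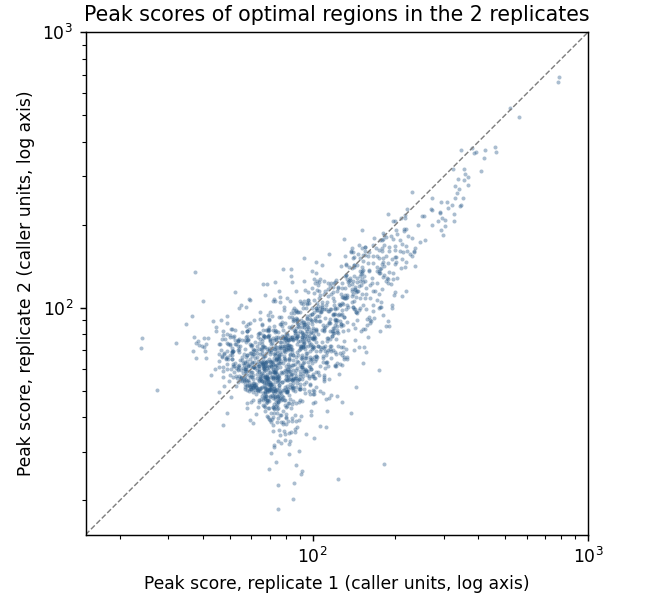
Peak score in replicate 1 (x axis) against replicate 2 (y axis), both in the caller's units on log axes, for the 1517 optimal regions with a summit within 100 bp in both replicate lists; each point is 1 region and the dashed line marks equal scores. The scores had a Spearman rho of 0.589 across these regions, which were selected by their pooled score. The strongest regions lie near the line. More points lie below the line than above it: the median log2 ratio of replicate 1 over replicate 2 was 0.263 (SD 0.482 across regions), with depth unknown.

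Optimal regions were concentrated outside exons and near gene starts. Summits fell in intergenic sequence in 53.8% of optimal regions and 29.8% of weaker regions, and in coding exons in 6.05% and 31.4% (two-sided Fisher's exact test over 5 classes of sequence, adjusted exact p = 6.09e-83 and 6.53e-132). Introns held 25.6% against 29.96% (adjusted exact p = 0.000206), and non-coding genes or pseudogenes outside protein-coding genes 10.5% against 3.92% (adjusted exact p = 2.58e-27). Untranslated exons, at 4.11% and 4.88%, did not pass the test (adjusted exact p = 0.187). This test over classes of sequence was not among those fixed before the data were examined.

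A protein-coding start lay within 500 bp of the summit in 606 optimal regions (37.8%, 35.4 to 40.2) and in 7069 weaker regions (25.6%, 25.1 to 26.1), an odds ratio of 1.76 (two-sided Fisher's exact p = 3.66e-25). The windows around starts cover 22.3% of the genome. Of the 606 promoter regions, 498 (82.2%) had their summit upstream of the nearest start, and the median position was -168 bp. Examples close to a start were mcm-4, a subunit of the replicative helicase (164 bp upstream), and atp-1, the alpha subunit of ATP synthase (14 bp upstream). Even so, 28.0% of optimal summits lay more than 2000 bp from every protein-coding start, against 33.2% of weaker ones.

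By chromosome, optimal regions were densest on X (19.3 per Mb) and III (18.6 per Mb) and lowest on IV, II and V (at most 14.4 per Mb). X held 342 optimal regions (21.3%, 19.3 to 23.4) against 18.3% of weaker regions (odds ratio 1.21, two-sided Fisher's exact p = 0.00256), and X makes up 17.7% of the nuclear genome. In the top 1604 regions of replicate 2 alone the excess on X did not pass the test (odds ratio 1.09, exact p = 0.193). Without regions near tRNA genes, an alternative added after the data were seen, it did not pass either (19.07% against 17.98%, odds ratio 1.08, exact p = 0.298). On the autosomes, the arms held 737 of 1262 optimal regions (58.4%, 55.6 to 61.1), below the 65.9% of weaker regions (odds ratio 0.728, exact p = 9.70e-08).

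Genes for ribosomal proteins, translation initiation and elongation factors, and heat shock proteins and chaperonins carried regions more often than other genes, whereas large families of chemosensory and F-box genes carried hardly any. In all, 684 of 19971 protein-coding genes (3.42%) had an optimal region within 500 bp of a start. Of the 27 gene lists, 9 were called, 5 of them higher and 4 lower than the other genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. No library of another factor was among the samples. Whether these regions, or those at non-coding RNA genes below, are particular to the tagged protein was therefore not tested.

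Against all genes, ribosomal protein genes had the highest share of the 27 lists: 22 of 78 had a region (28.2%, 18.6 to 39.5; adjusted exact p = 2.31e-13). They comprised 13 of 48 genes of the large subunit and 9 of 30 of the small subunit. The strongest were rpl-3, rpl-15, rpl-18A and rpl-35 (III:7854573-7854828, score 633.7). Counting only the gene with the nearest start, 13 of 78 had a region (16.7%), and the list was still called. That share was the same as that of translation factors (7 of 42, 16.7%) under this counting. Against only genes with any relaxed region, the share was 3.57 times that of the other genes, compared with 8.48 times against all genes, and was also a call. In that background their share (36.1%) was below those of translation factors (8 of 17, 47.1%) and of heat shock and chaperonin genes (14 of 33, 42.4%); differences between lists were not tested.

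The list of heat shock proteins and chaperonins had 14 of 63 genes with a region (22.2%, 12.7 to 34.5; adjusted exact p = 1.91e-07). The leading members were dnj-19, a DnaJ cochaperone gene that shares its region with nhr-47 (V:5505181-5505305, score 646.6), hsp-1, a constitutive Hsp70 gene (IV:17278478-17278707, 543.5), cct-8, a subunit of the cytosolic chaperonin (IV:1094296-1094428, 409.1), and dnj-13 (II:11545388-11545576, 345.8). In this list 3 of 8 cct genes, 6 of 29 dnj genes and 4 of 24 hsp genes had a region. With the nearest gene only, 7 of 63 had one (11.1%), 3.90 times the share of the other genes, and against genes with any relaxed region the share was 4.16 times theirs, compared with 6.60 times; both were calls.

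Translation initiation and elongation factors followed with 8 of 42 genes (19.05%, 8.60 to 34.1; adjusted exact p = 0.000516). Regions lay upstream of iff-2, an eIF5A gene (score 406.5), of both elongation factor 1-alpha genes, eef-1A.2 (298.9) and eef-1A.1 (274.4), and of eif-3.C (229.7). The nuclear genes of oxidative phosphorylation had 8 of 60 (13.3%, 5.94 to 24.6; adjusted exact p = 0.00434), led by the cytochrome oxidase subunits cox-5A (549.6), cox-5B (428.6) and cox-6B (263.9) and by atp-1 (280.4). Cell cycle and DNA replication genes had 7 of 73 (9.59%, 3.94 to 18.8; adjusted exact p = 0.0371): lin-35, the retinoblastoma homolog (242.7), pcn-1, the replication clamp (240.0), mcm-4 (168.6) and knl-3, a kinetochore gene (145.8), were the strongest. The last 2 lists lost their call in the stricter list, with replicate 1 alone and against genes with any relaxed region, and the cell cycle list also with the nearest gene only.

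Chemoreceptor genes were the largest list and had few regions, 5 of 1308 (0.382%, 0.124 to 0.890; adjusted exact p = 2.31e-13): srh-2, srh-269, sri-5, srh-16 and srw-85. Their share was 0.105 times that of the other genes, 0.0649 times without replicate 2 (3 genes), 0.149 times without replicate 1 (7 genes) and 0.254 times against genes with any relaxed region, a call in each case. F-box, MATH and BATH genes had 2 of 411 (0.487%, 0.0590 to 1.75; adjusted exact p = 0.000835), fbxb-72 and fbxb-85. C-type lectins had 1 of 239, clec-126 (0.418%, adjusted exact p = 0.0144), and neuropeptides and insulins 0 of 148, which allows a share of up to 2.46% (adjusted exact p = 0.0359). The F-box call was lost in the stricter list and against genes with any relaxed region, the lectin call in 4 of 7 alternatives, and the neuropeptide call was kept in 1 of 7.

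The other 18 lists did not pass. The closest were 10 genes of other transcription factor families (7.46%; fkh-7, a forkhead gene, 309.6, and ztf-7, 260.5), 5 of 50 neuronal genes (syd-2, a liprin, 201.9, unc-25, the glutamate decarboxylase, 193.4, egl-21, rgef-1 and cla-1) and 6 of 68 splicing genes (8.82%; snr-4, 292.1, and lsm-3, 158.0), each with an adjusted p of 0.0647. Each of these 3 passed in 3 or 4 of the 7 alternatives tried. Muscle genes had 4 of 51 (zyx-1, unc-112, act-4 and act-2; 7.84%, adjusted exact p = 0.184; 1 without replicate 1 and 0 in the stricter list), proteasome genes 3 of 33 (rpn-11, rpn-3 and pbs-1; 9.09%, adjusted exact p = 0.184), nuclear hormone receptors 11 of 269 (4.09%; nhr-47, 646.6, and nhr-57, 258.5), vacuolar ATPase genes 1 of 21 (vha-13; 0 without replicate 1 and 3 without replicate 2) and aminoacyl-tRNA synthetases 1 of 32 (ears-2).

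The remaining lists did not pass either. Cuticle collagens had 6 of 176 (3.41%; col-85 and col-71 first; 3 without replicate 1), patched, hedgehog-related and molting genes 3 of 99 (wrt-3, lin-42 and grl-4), the pharynx list 3 of 103 (pqn-51, 522.7, pqn-27 and pqn-70), ciliary genes 2 of 62 (tmem-107 and ift-43) and homeobox genes 2 of 96 (ceh-38 and unc-62). All 3 members of the pharynx list with a region entered it by the pqn symbol, and the annotation describes pqn-51 as a prion-like domain protein and pqn-27 as a MIF4G domain protein. Detoxification genes had 2 of 185 (gst-27 and cyp-33C3; 1.08%, adjusted exact p = 0.184; 1 of 185 without replicate 2), and intestine, germline and histone genes 1 each: asp-1 of 92 (0 without replicate 1 and 3 without replicate 2), puf-9 (score 507.2) of 88 and his-37 (508.9) of 72. Major sperm protein genes had 0 of 55, which allows up to 6.49%. Lists overlap in 17 genes, and neighbouring genes can share a region, so the lists are not fully independent.

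**Figure D2:**
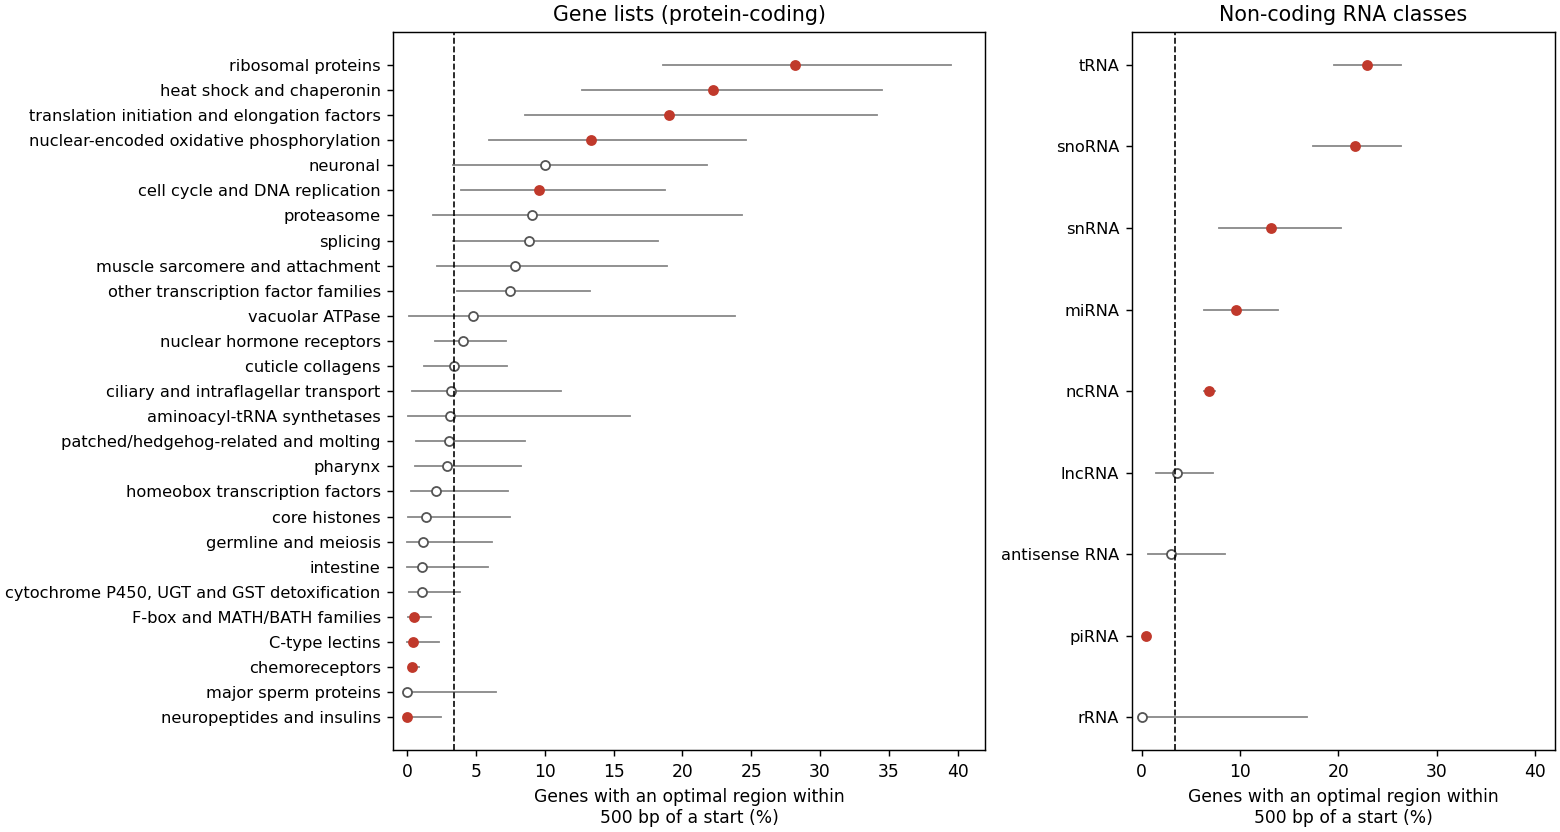
Share of genes with an optimal region within 500 bp of a transcript start (x axis, percent) for the 27 gene lists (left) and 9 classes of non-coding RNA genes (right); points are shares, bars are 95% exact intervals, filled points passed an adjusted p of 0.05 and the dashed line marks the 3.42% of protein-coding genes. Ribosomal protein genes (28.2%) and tRNA genes (22.9%) lie highest, and chemoreceptor genes (0.382%) and piRNA genes (0.436%) among the lowest.

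Genes for tRNAs and snoRNAs carried regions more often than protein-coding genes. Of 612 tRNA genes, 140 had a region (22.9%, 19.6 to 26.4; two-sided Fisher's exact test, adjusted exact p = 1.84e-66), and of 346 snoRNA genes, 75 did (21.7%, 17.4 to 26.4; adjusted exact p = 1.20e-35). The strongest at tRNA genes lay near the arginine tRNA gene C18A11.t2 on X (score 408.6) and between the divergent glutamate and glycine tRNA genes M02F4.t2 and M02F4.t1 (346.5). At snoRNA genes the strongest lay near C51F7.4 and C51F7.3 on V (414.4). Regions near tRNA genes made up 7.48% of optimal regions and 1.16% of weaker ones, and 99 of these 120 optimal regions had a summit window that was not single-copy in the genome.

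Among snRNA genes, 17 of 129 had a region (13.2%, 7.87 to 20.3; adjusted exact p = 4.60e-06), but among those more than 1000 bp from every protein-coding start only 5 of 71 did, which did not pass (adjusted exact p = 0.146). The strongest were at the spliced leader RNA genes sls-2.4 (I:4172206-4172315, score 552.0), sls-2.1 (II:5844865-5844974, 491.8) and sls-2.2 (II:5543598-5543707, 361.8). These genes encode RNAs that are trans-spliced onto messages of downstream operon genes. MicroRNA genes had 25 of 260 (9.62%, adjusted exact p = 8.07e-06), including mir-71 (311.5), mir-80 (271.8) and mir-5549, whose region is the one upstream of eef-1A.1. Unclassified non-coding RNA genes had 532 of 7762 (6.85%, adjusted exact p = 6.53e-33).

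The piRNA genes had 67 of 15363 (0.436%, adjusted exact p = 2.86e-98), below protein-coding genes, although the share of optimal regions near a piRNA gene (2.56%) did not differ from that of weaker regions (2.62%, exact p = 0.936). Neighbouring genes of a class can share a region: these 67 genes lay near 41 optimal regions, and the 532 unclassified genes near 410. Genes of a class are thus not independent, and the p-values of the non-coding classes can overstate the evidence. Long non-coding RNA genes (7 of 194), antisense RNA genes (3 of 100: anr-43, F48C1.15 and anr-5) and rRNA genes (0 of 20, which allows up to 16.8%) did not pass. Restricted to genes more than 1000 bp from every protein-coding start, the calls of the non-coding classes other than snRNA held.

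Summits were rich in GA repeats and in a GACGC-containing sequence. Of 2080 6-mers, 729 were more frequent at optimal summits than in their own flanks and 491 less frequent. With weaker summits as the control in place of flanks, 583 were more frequent, and with an equal number of weaker summits matched on GC content, added after the data were seen, 252 were, not all of them among the 729. GAGAGA was present within 75 bp of 34.5% of summits (32.2 to 36.9) and in 8.42% of flank windows (7.10 to 9.88; exact McNemar test, adjusted exact p = 2.17e-70), and AGAGAG in 31.7% and 6.98% (adjusted exact p = 1.69e-69). AGAGAC was present at 23.8% against 5.05%, CGTCTC at 21.6% against 4.61% and GACGCA at 17.96% against 3.05% (adjusted exact p = 5.27e-50, 2.94e-47 and 1.47e-44).

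At least 1 of these 5 6-mers was present at 56.0% of optimal summits, 25.5% of weaker summits and 17.5% of flanks. These 6-mers were chosen for their low p between the same summits and flanks. The excess over flanks follows from that choice, and its size is overstated. Ordered by score in 4 groups of 401 regions, the share was 68.6% in the strongest group, then 56.4%, 50.1% and 48.9%. The most depleted 6-mers were AT-rich: AAAATT was present at 20.8% of summits and 55.05% of flanks, TTAAAA at 10.04% and 39.3%, and AAAAAT at 30.6% and 62.4%. Mean GC content was 47.2% at optimal summits (SD 7.57 across regions), 40.9% at weaker summits (SD 7.69) and 35.2% in flanks (SD 7.89).

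**Figure D3:**
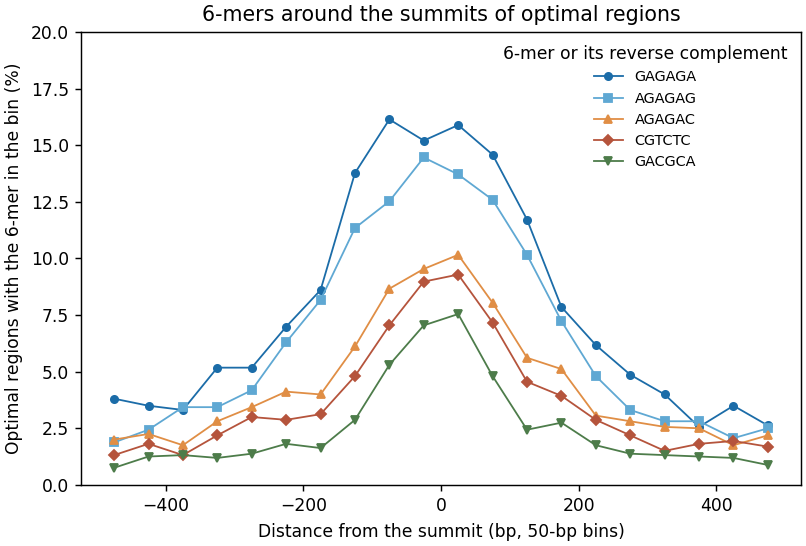
Share of the 1604 optimal regions (y axis, percent) with each of the 5 named 6-mers or its reverse complement in 50-bp bins by distance from the summit (x axis, bp); each line is 1 6-mer. Within 50 bp after the summit GAGAGA is present in 15.9% of regions and GACGCA in 7.54%, and both fall towards the flanks.

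The tagged gene and the rescue marker were examined because the strain carries extra copies of both. The tagged gene, znf-782 (IV:1058076-1067525, minus strand), had 5 relaxed pooled regions within 20 kb, at percentile 6.30 of protein-coding genes, and no optimal region. Its nearest optimal summit, 26834 bp away, was that of cct-8. For unc-119 (III:10902641-10908935, plus strand) there were 9 relaxed regions within 20 kb, at percentile 25.1, and the nearest optimal summit was 53622 bp away. The percentile of znf-782 was 12.9 within 10 kb, and that of unc-119 was 8.68 without replicate 2. Neither locus stood above the median of 2.80 relaxed regions per 10 kb over genes (1.01 at znf-782 and 1.94 at unc-119). These values count called regions and do not measure coverage. A broad rise in coverage from the extra copies need not add regions, so such a rise was not tested.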

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

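The alternatives that removed regions near tRNA or snoRNA genes, kept single-copy windows, removed multi-copy windows away from tRNA genes, matched weaker regions on GC content or kept non-coding genes away from protein-coding starts were chosen only after the data were seen; the others were planned. The promoter share (odds ratio 1.53 to 2.68 in 8 alternatives) and the arm share (0.698 to 0.726 in 5) kept their direction and their call, as did the replicate overlap and all 5 named 6-mers in 8 alternatives. The alternatives for the 6-mers reused largely the summits on which they were chosen, so they are not separate support. The X share was kept without multi-copy windows away from tRNA genes (odds ratio 1.18) and lost without regions near tRNA genes (odds ratio 1.08) and with single-copy windows (1.08), and ran from 1.09, no longer a call, without replicate 1 to 1.21 without replicate 2. The rank correlation was 0.641 for summits within 50 bp, and neither it nor the overlap can be computed without a replicate. The number of called lists was 5 in the stricter list and 4 against genes with any relaxed region, and 5 to 11 with 1 replicate left out, against 9; of the left-out replicates, leaving out replicate 2 gave the 5. Non-coding classes stayed at 6 calls, except 5 away from protein-coding starts. Against GC-matched weaker regions 252 6-mers were enriched, not all of them among the 729, a setting that also replaced the flanks (583 against all weaker regions). The percentile of znf-782 was 12.9 at 10 kb, 8.52 at 40 kb and 5.22 to 6.04 with 1 replicate left out, and that of unc-119 8.68 to 25.4. For single lists, values are the share of the list's genes with a region over that of other genes. In the stricter list calls were lost for C-type lectins (0.229), F-box genes (0.265), neuropeptides (0), cell cycle (2.28) and oxidative phosphorylation (3.72), and other transcription factors gained one (3.35). Against genes with any relaxed region the same 5 lost theirs (0.160, 0.278, 0, 2.06 and 2.36). With the nearest gene only, lectins (0.144), neuropeptides (0) and cell cycle (2.40) lost their call and other transcription factors (2.62) and neuronal genes (3.50) gained one. Within 1000 bp neuropeptides (0.409) lost theirs, and neuronal (2.85) and splicing genes (2.40) gained one, as both did from 500 bp upstream to 100 bp downstream (3.20 and 2.83). With 1 replicate left out the ratio ran from 0 to 0.250 for lectins, 2.07 to 2.85 for cell cycle, 0.202 to 0.397 for neuropeptides, 2.52 to 4.47 for oxidative phosphorylation, 3.03 to 3.56 for neuronal, 2.27 to 2.45 for other transcription factors and 2.67 to 3.06 for splicing genes; for lists called in neither case it ran from 0 to 0.982 for intestine and from 0.162 to 0.317 for detoxification genes. Lists and classes that never passed changed sides of 1, none with an adjusted p under 0.05. In the stricter list these were molting (1.12), nuclear hormone receptors (0.821), homeobox (1.15), muscle (0), pharynx (1.07), vacuolar ATPase (0) and aminoacyl-tRNA synthetases (1.73). With 1 replicate left out they were collagens (0.501 to 1.20), molting (0.912 to 1.19), muscle (0.578 to 1.78), pharynx (0.877 to 1.15) and vacuolar ATPase (0 to 4.32). Within 1000 bp they were collagens (1.04), molting (1.02) and pharynx (1.58), and in the asymmetric window ciliary genes (1.03). With the nearest gene only they were molting (1.05), pharynx (1.01) and synthetases (1.09), and against genes with any relaxed region vacuolar ATPase (0.743). Antisense RNA genes were at 1.11 in the stricter list, 1.82 within 1000 bp and 1.10 away from protein-coding starts, and long non-coding RNA genes at 0.872 there. Fewer regions in the stricter list and fewer genes in the relaxed background leave less power; otherwise the cause was not tested. Depth is unknown, and its effect on the lists was not tested.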

Other observations

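The tests of the X share without regions near tRNA genes, of single-copy windows, of GC-matched regions, of tRNA genes by copy number and by distance from protein-coding starts, and of the genes with several regions were chosen only after the data were seen.

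Some genes held several optimal summits, some of them in overlapping regions. T28B11.1 on V (10712165 to 10732422) held 8 summits, ppfr-1 on I held 7, zfp-1, a zinc finger gene on III, held 6, and let-526, a gene for an ARID domain protein, and fkh-7 held 5 each. The densest 20 kb stretches held 9 regions each, at V:724008-731494 around icl-1, which encodes the glyoxylate cycle enzymes, and srh-2, and at V:10711908-10729668 across T28B11.1, where 24 unclassified non-coding RNA genes are annotated. In 100 random placements of the optimal regions, the highest number in any 20 kb was 6, so that the counts in zfp-1, let-526 and fkh-7 do not exceed that number. With overlapping regions counted once, T28B11.1 held 7, ppfr-1 only 5, which does not exceed it either, and each of the densest stretches 8. The srh-2 and fbxb-72 regions, members of families that otherwise had few, both lie at the icl-1 stretch. Intragenic regions of ppfr-1 surround mir-71, and the region with score 1438 overlaps F16A11.7 and F16A11.9.

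tRNA genes of most isotypes had regions, from 5 of 13 cysteine genes (38.5%) down to 2 of 20 asparagine and 2 of 20 histidine genes and 1 of 12 tryptophan genes (8.33%). The larger families lay between, among them glycine (16 of 55), lysine (9 of 46), arginine (14 of 44), proline (11 of 42) and glutamate (8 of 41). Differences between isotypes were not tested.

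The first pattern is the excess of optimal regions on X. X holds 45.1% of tRNA genes and 59 of the 120 optimal regions near them. Without regions near tRNA genes the odds ratio fell from 1.21 to 1.08 (exact p = 0.298), and with single-copy windows only it was also 1.08 (exact p = 0.294). Of the 120 regions, 99 have multi-copy windows, and removing only multi-copy windows away from tRNA genes left an odds ratio of 1.18 (exact p = 0.0115). Because 59 of the 120 regions lie on X, removing them had to lower the odds ratio. Unclassified non-coding RNA genes, with 2520 of 7762 on X, were not removed in the same way. That tRNA genes carry the excess is thus a candidate explanation, but these values do not single them out. Copy number inside those genes is left open, and no biological explanation was tested.

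The second pattern is the share of tRNA genes with a region. Regions placed at nearby protein-coding starts would leave few at isolated tRNA genes, but 87 of 393 tRNA genes more than 1000 bp from every such start had one (22.1%, 18.1 to 26.6; exact p = 3.68e-42), which argues against this. Reads shared between near-identical copies stay open: tRNA genes whose sequence occurs once had a region in 23 of 140 cases (16.4%, 10.7 to 23.6), above the 3.42% of protein-coding genes, against 24.8% of those with more copies (exact p = 0.0396). Most of the 140 still share 31-mers with other sites, however, and of the 22 with none shared only 1 had a region (4.55%, 0.115 to 22.8), too few to decide. No biological explanation was tested, because the design holds 1 group.

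The third pattern is the GA-rich and GACGCA-type 6-mers, which overlap in sequence and need not be separate. Against weaker regions matched on GC content (means of 47.2% in both), all 5 6-mers stayed enriched, GAGAGA at 34.5% against 14.7% and GACGCA at 17.96% against 5.24% (adjusted exact p = 1.15e-36 and 5.57e-28). With only the 1404 summit windows (87.5%) that are single-copy, all 5 stayed enriched against flanks. Multi-copy sequence thus does not account for these 6-mers as the whole cause, nor did GC content against these controls. The controls were not matched on class of sequence, however. Coding exons held 31.4% of all weaker summits and 6.05% of optimal ones, so GC content was not tested apart from class. Whether the tagged protein binds them, or whether they mark open promoters shared with other factors, was not tested here and stays a hypothesis.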
